A study of Spodoptera frugiperda with 18 samples.

How the data were processed

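Small RNA libraries of the fall armyworm, Spodoptera frugiperda, were made from total RNA with a TruSeq small RNA kit and sequenced on an Illumina HiSeq instrument, per the labels' protocols, which speak of 9 libraries where the series has 18 and do not say which. The authors deposited 1 table of raw counts per miRNA for all 18 libraries, with a name and a sequence for each row; the values are whole numbers with different totals per library. The aligner, the miRNA caller and any genome build are not given in the sources used here, and no genome was used here, so no coordinates are given. Species names begin with sfr-, family names come from other animals and end in -x, -y or -z, and 177 rows are predictions. Among family rows with a species counterpart, all that shared 12 bases with a single arm did so with the 5p arm for -x (23 rows) and with the 3p arm for -y (23 rows), and the letters were read that way.

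The table has 741 rows, and 61 sequences are listed more than once. Rows with the same sequence and the same counts were merged, leaving 660, and 10 sequences listed with unequal counts stayed as they were. 276 rows have a near copy, defined as at most 2 differences over at least 18 aligned bases, and the values of these are uncertain where counting could have split reads. Every row has at least 10 counts over the 18 libraries. Rows with family names known from vertebrates were listed after the data had been seen. The list held 84 rows at first, and after its first results had been seen the rows with a near copy among other names were taken out, leaving 78; their sequences are not given.

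The groups were egg, larva, prepupa, female pupa, male pupa, female adult and male adult. Tests were edgeR's quasi-likelihood test (edgeR 4.0.16, R 4.3.3) with robust dispersions and TMM factors, which ran from 0.640 to 1.47. miRNAs with a mean of at least 10 counts over the libraries of a fit were tested, and p-values were adjusted by the Benjamini-Hochberg method within each comparison, with a threshold of 0.05. The quasi-likelihood test gives no standard error. Each SE printed with its log2 fold change is the size of that change divided by the square root of the F statistic, and is approximate. Life stages were compared in 1 fit of the 16 larval, pupal and adult libraries. Sexes, successive ages and the difference of the sex effect between adults and pupae were tested over the 10 pupal and adult libraries with terms for age and sex. The larval trend used instar number as a linear term over 6 libraries. Steps between single libraries used a minimum of 100 CPM in either library, a 2-fold change and 1 CPM added before the log2, with no test. Levels are CPM with TMM factors over the 18 libraries.

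The comparisons, tests, alternatives, lists and the rule for named miRNAs were fixed before the data were examined. For each tested comparison the rule took, among miRNAs past the threshold with a mean of at least 100 CPM, the 10 largest rises and the 10 largest falls, and members of the lists could also be named. The lists were the let-7 complex, 5 clusters (miR-277, miR-317 and miR-34; miR-71, miR-2 and miR-13; miR-275 and miR-305; miR-12, miR-283 and miR-304; miR-9, miR-79 and miR-306), muscle, neuronal and sensory, growth, apoptosis and fat metabolism, moulting and ecdysone, Hox cluster, embryo, ovary and germline, testis, Lepidoptera-restricted and plant diet; no row matched the testis or plant lists. Alternatives were DESeq2's size factors, library totals, no filter, the DESeq2 Wald test (DESeq2 1.42.0) and limma on log2 CPM (limma 3.58.1). Others were a 2-fold minimum, leaving out each library in turn, and other designs. More, named below, were added after the data had been seen. Pseudocounts other than 1 had been planned only for normalized values and were not run. Intervals of shares are exact 95% binomial intervals. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were used.

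Each test was tested on simulated data with changed rows of known size. Many rows were changed at once, so that for females against males 254 of the 372 tested rows were unchanged. Apart from these changes all libraries had the same mean shares, with no age effects. Where fewer rows truly change, the adjusted threshold is stricter, so the percentages need not hold for the real comparisons. For pupae against larvae, with 350 rows tested, 89.4% of 16-fold and 52.8% of 4-fold changes were called. For adults against pupae, with 345 rows tested, 76.3% of 16-fold and 44.1% of 4-fold changes were called. For adults against larvae, with 342 rows tested, 88.6% of 16-fold and 42.4% of 4-fold changes were called. For females against males, with 372 rows tested, 97.7% of 16-fold and 82.9% of 4-fold changes were called. For pupal day 4 against day 1, with 371 rows tested, 79.5% of 16-fold and 17.1% of 4-fold changes were called. For pupal day 7 against day 4, with 368 rows tested, 80% of 16-fold and 21.1% of 4-fold changes were called. For adult day 1 against pupal day 7, with 364 rows tested, 80% of 16-fold and 30.6% of 4-fold changes were called. For adult day 4 against day 1, with 369 rows tested, 78% of 16-fold and 19.4% of 4-fold changes were called. For the sex difference, with 364 rows tested, 92.5% of 16-fold and 26.5% of 4-fold changes were called. For the larval trend, with 243 rows tested and folds taken from instar 1 to instar 6, 31% of 16-fold and 21.4% of 4-fold changes were called. With 2-fold changes, 20.6% were called for females against males, 14.7% for pupae against larvae, and 0% to 7.89% in the other 8 comparisons, with 0% for pupal day 4 against day 1, adult day 4 against day 1 and the larval trend; 0 to 2 unchanged rows were called in each comparison. Counts per library ran from 230451 to 4808814.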

Results

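Small RNA was sequenced from whole fall armyworms, Spodoptera frugiperda, a moth whose caterpillars feed on maize and other crops, from egg to adult. The 18 libraries cover the egg, larval instars 1 to 6, the prepupa, female and male pupae on days 1, 4 and 7, and female and male adults on days 1 and 4. Every stage, sex and age has 1 library. Libraries of different instars, ages or sexes therefore served as the replicates of a life stage, with 6 larvae, 6 pupae and 4 adults, and the spread given with each mean holds differences of age and sex. The labels do not state whether the libraries came from separate cultures or pools, so the p-values measure only the spread between these samples. Counts summed over miRNAs ran from 230451 in instar 3 to 4808814 in the prepupa, with at most 796582 in the 9 shallowest libraries, which were the egg, all 6 instars and the male pupae of days 4 and 7, and at least 1197762 in the others. Levels are CPM, counts scaled to a common library size and normalised for composition; against plain library totals, 3 counts made 0.624 CPM in the prepupa and 13.02 CPM in instar 3. Intervals and floors cover counting error only, because reads without molecular identifiers are not independent molecules.

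The miRNA with the highest mean was bantam-y in larvae and adults and miR-100-x in pupae. In the egg, sfr-miR-10-5p, which lies in the Hox gene cluster of insects, led with 139310 CPM, ahead of miR-998-y with 109370 CPM, sfr-miR-11-3p with 54587 CPM and miR-92-z with 52430 CPM. In larvae, bantam-y, a growth-promoting and anti-apoptotic miRNA in flies, led with 109420 ± 17323 CPM (SD, n = 6). In pupae, miR-100-x, a member of the let-7 complex, led with 237330 ± 51540 CPM (SD, n = 6), followed by miR-276-y with 123620 ± 33112 CPM (SD, n = 6). Adults had 169310 ± 21016 CPM (SD, n = 4) of bantam-y, 164740 ± 42868 CPM (SD, n = 4) of miR-100-x, 98257 ± 24711 CPM (SD, n = 4) of miR-276-y and 84032 ± 24986 CPM (SD, n = 4) of sfr-miR-277-3p. miR-100-x led in both day 1 adult libraries and bantam-y in both day 4 adult libraries. Among the larvae, sfr-miR-10-5p led in instar 1, bantam-y in instars 2, 3 and 4, and miR-100-x in instars 5 and 6. miRNAs predicted from these reads, which carry no family name, took 29.6% of the egg counts and between 2.04% and 6.85% in the other 17 libraries. A median of 270.5 miRNAs per library had at least 10 counts.

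**Figure D1:**
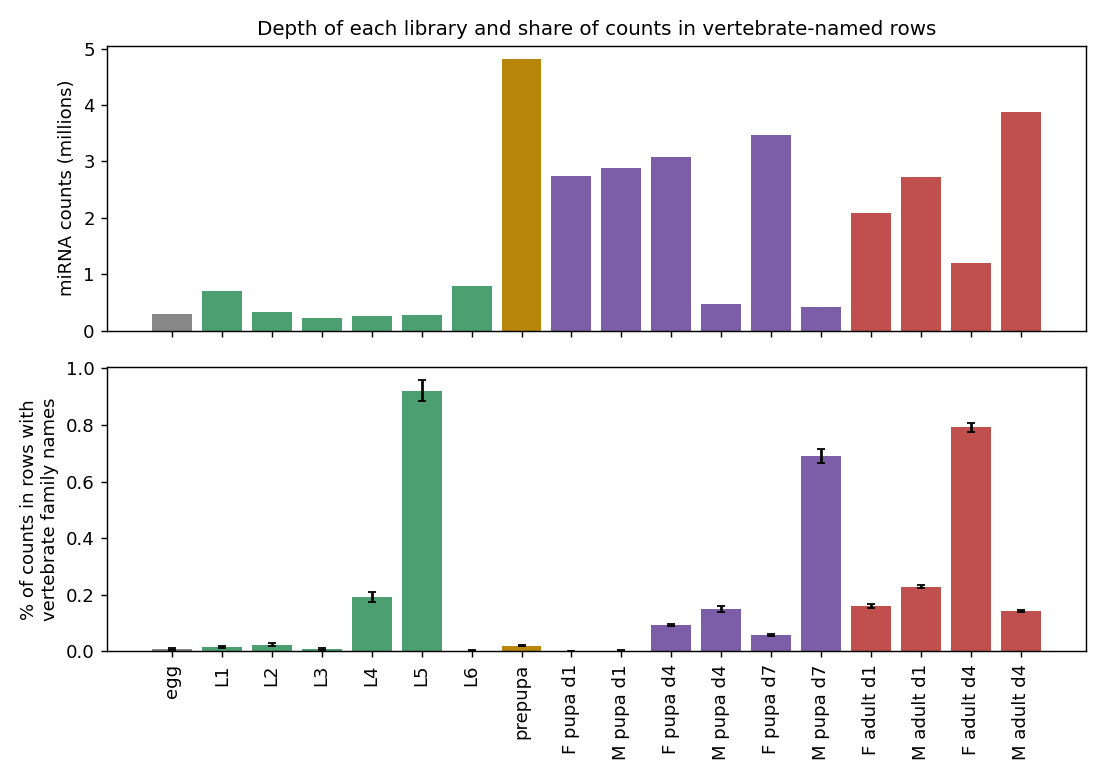
Depth of each library (top, miRNA counts) and percent of its counts in miRNAs with family names known from vertebrates (bottom, bars with exact 95% binomial intervals) for the 18 libraries; L1 to L6 are instars, F and M are female and male, d is the day. Depth ran from 230451 to 4808814 counts, and the share was highest in instar 5 at 0.920%.

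Pupae were compared with larvae to find the miRNAs that differ across metamorphosis. sfr-miR-2765-5p averaged 85.8 ± 134 CPM (SD, n = 6) in larvae and 5438 ± 5488 CPM (SD, n = 6) in pupae, a log2 fold change of 5.69, SE 1.24, adjusted p = 0.00303 by edgeR. let-7-x, the temporal regulator that rises at metamorphosis in flies, went from 2215 ± 2688 CPM (SD, n = 6) to 31598 ± 9762 CPM (SD, n = 6) (log2 3.53, SE 1.07, adjusted p = 0.0193 by edgeR), and its other arm let-7-y rose by 2.97 on the log2 scale. In the opposite direction, miR-11980-z averaged 649 ± 467 CPM (SD, n = 6) in larvae and 0.467 ± 0.738 CPM (SD, n = 6) in pupae (adjusted p = 1.47e-05, edgeR). miR-281-x fell from 748 ± 358 CPM (SD, n = 6) to 77.2 ± 27.7 CPM (SD, n = 6), a log2 fold change of -3.52, SE 0.36, adjusted p = 1.47e-05 by edgeR. sfr-miR-34-5p, which responds to ecdysone in flies, went from 162 ± 180.3 CPM (SD, n = 6) to 20.98 ± 16.1 CPM (SD, n = 6) (log2 -3.20, SE 0.76, adjusted p = 0.00541 by edgeR).

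Among the other named miRNAs, those higher in pupae were miR-11625-x, miR-98-x, the predicted miRNA of sequence CATCGACATCGTCAGAAACT, sfr-miR-10505-3p, miR-71-y, miR-193-y and sfr-miR-307-3p, with log2 fold changes from 2.38 to 4.04. Those higher in larvae were miR-7115-x, sfr-miR-6094-5p, miR-927-x, sfr-miR-274-5p, miR-282-x, miR-750-x and sfr-miR-10499a-3p, with log2 fold changes from -5.62 to -3.19. miR-98-x and let-7-x are near copies in sequence, as are miR-281-x and sfr-miR-281-5p, so that counting may have split reads between them.

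By list, let-7 complex members rose in 2 of 7 tested rows, let-7-x and let-7-y (2 adjusted over the list alone), while miR-100-x at log2 1.95 had an adjusted p of 0.0889 by edgeR. In the cluster of miR-71, miR-2 and miR-13, 6 of 11 rose (6 adjusted over the list alone), led by miR-71-y and sfr-miR-2b-3p at 1.52. Of the 14 moulting and ecdysone miRNAs, 5 fell, 4 of them rows of miR-281 and the other sfr-miR-34-5p, and miR-252-x rose by 2.05 on the log2 scale (5 and 1 adjusted over the list alone). Of 4 muscle rows, 2 fell, miR-1-y (log2 -1.08) and miR-133-z (log2 -1.38), with 2 adjusted over the list alone. Of 12 neuronal and sensory rows, 2 rows of miR-263 rose, and miR-124-y (log2 -2.91) and miR-137-y (log2 -2.35) fell, the same counts adjusted over the list alone. The Hox cluster list split, with 4 of 12 higher, among them iab-4-x, and 4 lower, among them sfr-miR-10-5p (5 and 5 adjusted over the list alone). These 12 rows are not 12 separate miRNAs. iab-4-x and miR-iab-4-1-x had nearly equal log2 changes in adults against pupae (-1.282 and -1.280), and miR-10 has several rows. Among 30 miRNAs restricted to Lepidoptera, 6 rose and 9 fell (6 and 11 adjusted over the list alone).

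In all, 120 of 320 tested miRNAs passed an adjusted p of 0.05 in edgeR's quasi-likelihood test, 62 higher and 58 lower in pupae. Scaling by library totals alone moved the median log2 change of all miRNAs from -0.00771 to -0.31 and gave 44 higher and 78 lower. All 6 larval libraries were among the 9 shallowest, against 2 of the 6 pupal libraries.

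**Figure D2:**
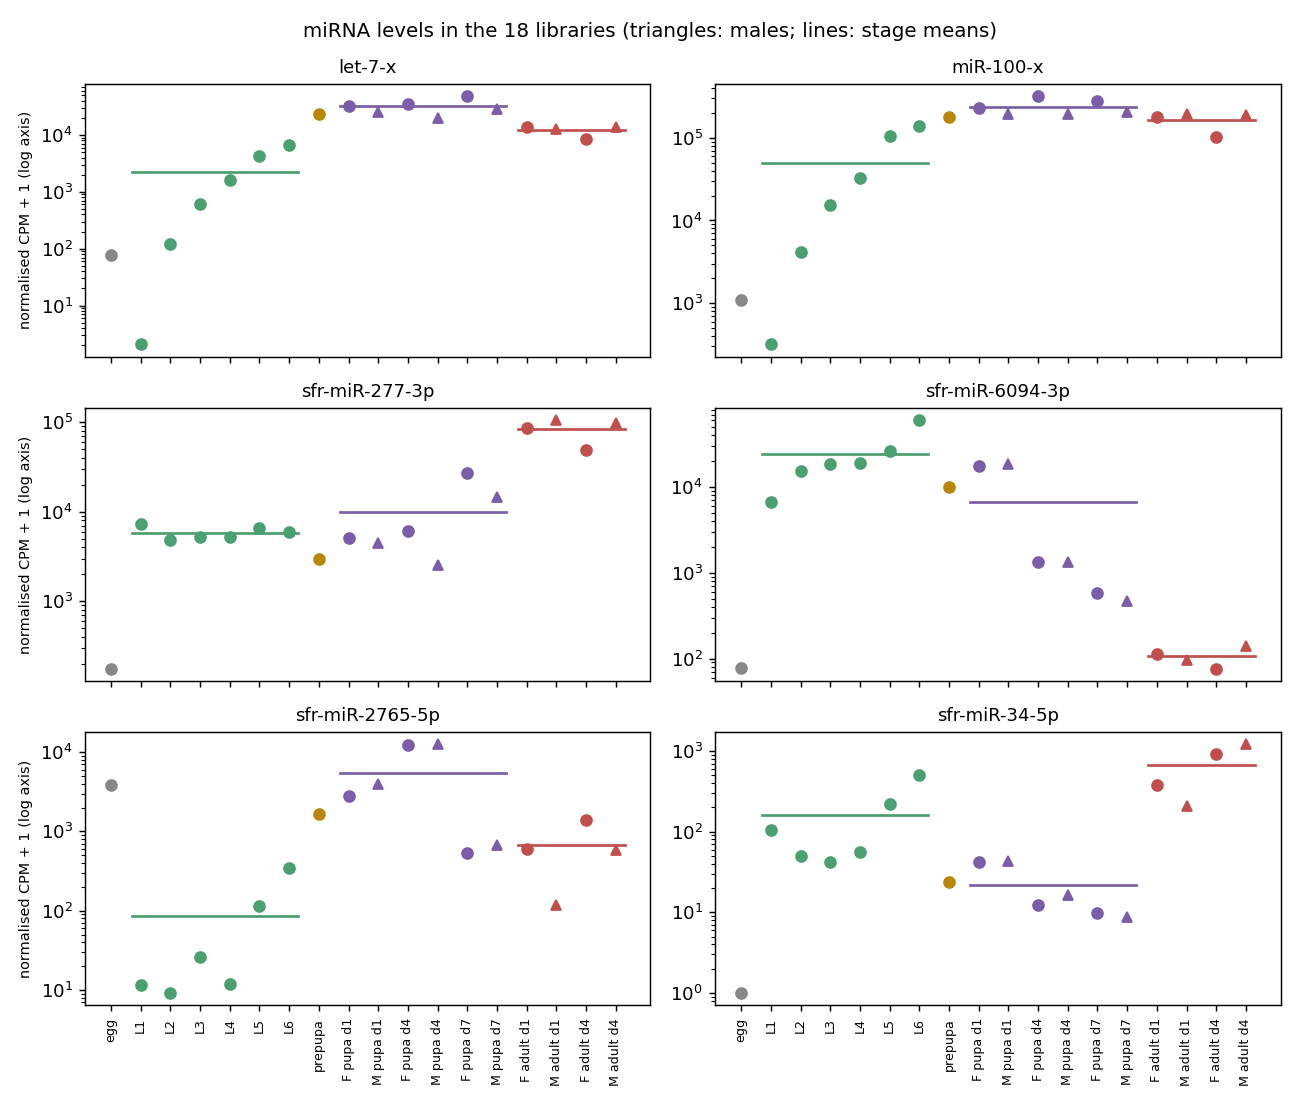
Normalised CPM plus 1 (log axis) of 6 miRNAs in the 18 libraries in developmental order; each point is 1 library, triangles are males and lines are the means of larvae, pupae and adults. let-7-x climbed from 1.07 CPM in instar 1 to 6651 CPM in instar 6, and sfr-miR-277-3p averaged 84032 CPM in adults.

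Adults were compared with pupae across eclosion. sfr-miR-277-3p, a miRNA of branched-chain amino acid metabolism in flies, rose from 10031 ± 9440.4 CPM (SD, n = 6) to 84032 ± 24986 CPM (SD, n = 4), a log2 fold change of 2.99, SE 0.52, adjusted p = 0.00143 by edgeR. sfr-miR-34-5p, encoded in the same cluster in flies, rose from 20.98 ± 16.1 CPM (SD, n = 6) to 679.5 ± 465 CPM (SD, n = 4) (log2 4.93, SE 0.85, adjusted p = 0.00143 by edgeR). sfr-miR-6094-3p fell from 6716 ± 8983 CPM (SD, n = 6) to 105 ± 26.3 CPM (SD, n = 4), with a log2 fold change of -6.01, SE 1.26, adjusted p = 0.00356 by edgeR. miR-305-x fell from 23485 ± 11247 CPM (SD, n = 6) to 1677 ± 639 CPM (SD, n = 4) (log2 -3.80, SE 0.70, adjusted p = 0.00176 by edgeR). sfr-miR-375-3p had 8.74 ± 7.76 CPM (SD, n = 6) in pupae and 1354 ± 1809.8 CPM (SD, n = 4) in adults (log2 7.13, SE 1.27, adjusted p = 0.00143 by edgeR), with 1315 and 3926 CPM in the male adults against 57.1 and 118 CPM in the females.

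All 11 tested rows of the miR-71, miR-2 and miR-13 cluster fell (11 adjusted over the list alone), from -1.08 for sfr-miR-2b-3p to -3.24 for sfr-miR-2c-5p on the log2 scale. In the cluster of miR-277, miR-317 and miR-34, 5 of 9 rose (7 adjusted over the list alone), including miR-277-y at 3.93 and miR-317-y at 3.32. In the cluster of miR-275 and miR-305, 2 of 3 fell, both of them rows of miR-305, with 2 adjusted over the list alone. Of the 14 moulting and ecdysone miRNAs, 6 rose (6 adjusted over the list alone), 4 of them rows of miR-281. Of 10 growth and fat miRNAs, 2 rose, bantam-y by 0.73 and sfr-miR-14-3p by 1.39 on the log2 scale, with 2 adjusted over the list alone. Of 12 neuronal and sensory rows, 2 fell, miR-7-x and miR-263-x (3 lower and 1 higher adjusted over the list alone). In the cluster of miR-9, miR-79 and miR-306, miR-9-z alone of 6 fell, with a log2 change of -2.29 (1 adjusted over the list alone). miR-12-x rose by 1.15 and was the single member of 4 in the cluster of miR-12, miR-283 and miR-304 to pass, also adjusted over the list alone. Further named miRNAs passed the test with unlike levels in the sexes, each given here for adult days 1 and 4. sfr-miR-375-5p had 5497 and 9964 CPM in males and 129.9 and 144 CPM in females, and the predicted miRNA of sequence TTTGTTCGCCCCGGCTCGAGTCG, a near copy of sfr-miR-375-3p, 6927 and 14030 CPM in males and 145 and 234 CPM in females. The predicted miRNA of sequence TAGCAAAATTCGGACTCACGTGTTT had 109 and 1258 CPM in females and 0.428 and 0.306 CPM in males. The predicted miRNAs of sequences CCCAGTGTTGTGTTAACGATCT and CCCAGTGTCGTGTTAACGATCT had 237 and 1074 CPM and 3308 and 10382 CPM in females, and 40.3 and 70.4 CPM and 571 and 742 CPM in males. Lower in adults were miR-6094-z, sfr-miR-6094-5p, miR-305-y, miR-71-y and sfr-miR-13b-3p.

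edgeR called 75 of 320 miRNAs, 36 higher and 39 lower in adults. Without the day 4 female adult, 29 miRNAs were called, all of them among the 75.

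Adults differed from larvae in 106 of 320 tested miRNAs by edgeR, 56 higher and 50 lower. sfr-miR-277-3p had 5857 ± 932 CPM (SD, n = 6) in larvae and was higher in adults by a log2 fold change of 3.57, SE 0.53, adjusted p = 0.000404 by edgeR. sfr-miR-285-3p averaged 24.9 ± 35.3 CPM (SD, n = 6) in larvae and 663 ± 389 CPM (SD, n = 4) in adults (log2 4.49, SE 1.16, adjusted p = 0.00815 by edgeR). sfr-miR-6094-3p went from 24369 ± 18662 CPM (SD, n = 6) in larvae to the adult level given above, a log2 fold change of -8.18, SE 1.39, adjusted p = 0.00108 by edgeR. miR-1175-x, miR-750-x, miR-137-y, miR-6497-y and sfr-miR-10472-5p were also lower in adults, from -6.05 for miR-6497-y to -2.84 for sfr-miR-10472-5p on the log2 scale. Of 7 embryonic and maternal miRNAs, 3 rose, all rows of miR-92, and 2 fell, miR-31-x and miR-9-z, the same counts adjusted over the list alone. On adult days 1 and 4, miR-92-z had 1127 and 5382 CPM in females and 202 and 188 CPM in males, sfr-miR-92a-3p 634 and 2227 CPM and 185 and 189 CPM, and miR-92-y 22.5 and 319.8 CPM and 10.7 and 5.20 CPM, against 309, 171 and 0 CPM in instar 6. Of 4 ovary and germline rows, 2 rose, both of them rows of miR-989 and near copies of each other (2 adjusted over the list alone). miR-989-z had 5168 and 18193 CPM in the female adults and 1.71 and 1.22 CPM in the males.

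Females were compared with males over 5 ages, pupal days 1, 4 and 7 and adult days 1 and 4, with age as a block. miR-989-y, an ovary miRNA in insects, was higher in females, with 37.6 CPM at pupal day 7, 223 CPM at adult day 1 and 1153 CPM at adult day 4, against at most 0.428 CPM in the 5 males. The fitted log2 difference of 10.92, SE 0.93, adjusted p = 0.00212 by edgeR, depends on the prior count, as the 5 males hold 1 count together. miR-3338-y was higher in males at every age, from 2514 CPM at pupal day 1 to 873 CPM at adult day 4, against 3.55 to 13.6 CPM in females (log2 -7.76, SE 0.72, adjusted p = 0.00319 by edgeR). These were the 2 of 344 miRNAs that edgeR called, whereas 42 had an unadjusted p under 0.05 and DESeq2 called 21. Of 4 ovary and germline rows, miR-989-y rose over all miRNAs and 2 rows of miR-989 did when adjusted over the list alone. The sequence of miR-989-y lies within that of miR-989-z, so the 2 are not separate miRNAs. miR-989-z was the more abundant, with 18193 CPM in the day 4 female adult, and was not called over all miRNAs. The count was 14 and 6 without the day 1 female or male pupa, 9 without either day 4 adult, and 1 without the day 7 female pupa or either day 1 adult. It was 0 without the male pupae of days 4 and 7 together, 12 without vertebrate-named miRNAs, 16 with no filter, 10 with thinned counts, 5 with no age block and 4 with rows unmerged.

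**Figure D3:**
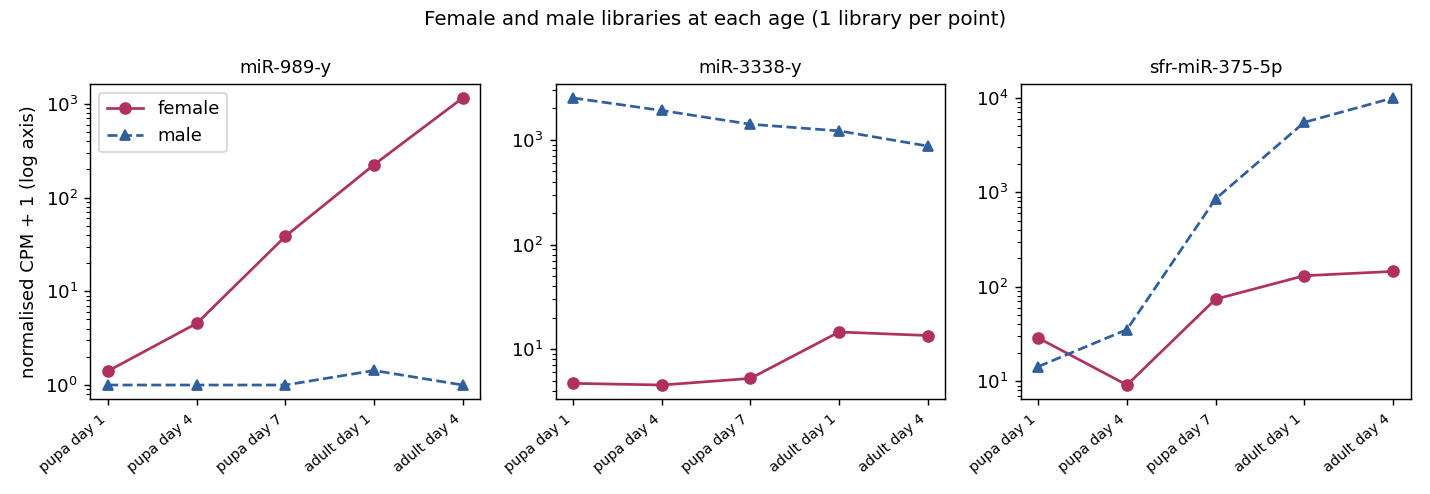
Normalised CPM plus 1 (log axis) of miR-989-y, miR-3338-y and sfr-miR-375-5p in female (circles) and male (triangles) libraries at 5 ages, 1 library per point. miR-989-y reached 1153 CPM in the day 4 female, and sfr-miR-375-5p reached 9964 CPM in the day 4 male.

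The sex difference itself was compared between adults and pupae. It was larger in adults, towards females, for miR-2765-z (log2 difference 8.04, SE 0.75, adjusted p = 0.00271 by edgeR), which had 1124 CPM in the day 4 female adult and 4.29 CPM in the male. miR-989-z, miR-998-y and sfr-miR-2765-5p moved the same way, as did the predicted miRNAs of sequences TATTTTTGTATTACATGGCCCA and CCCAGTGTCGTGTTAACGATCT. miR-3338-y kept its male excess, which was smaller in adults (log2 difference 2.59). miR-1-y, a muscle miRNA, had a log2 difference of -1.31 towards males in adults, 1 of the 4 muscle rows, also adjusted over the list alone, but -0.93 (edgeR adjusted p = 0.133) with DESeq2's size factors and -0.60 (adjusted p = 0.207) with library totals; its adjusted p ran from 0.00683 to 0.531 over its alternatives. Of the 12 Hox cluster rows, miR-iab-8-x alone passed (log2 difference -5.74, SE 0.93, adjusted p = 0.0469 by edgeR), with 720.3 CPM in the day 4 male adult and 4.42 CPM in the female. edgeR called 11 of 344, 9 towards females and 2 towards males. The median over all miRNAs was -0.35, 0.0232 with DESeq2's size factors and 0.36 with library totals. The count was 58 and 50 without the day 1 female or male adult, 1 and 4 without the day 1 female or male pupa, 2 without the day 7 female pupa, 4 without the day 4 male adult, and 0 without the day 4 female adult or either day 4 pupa. It was 40 with the DESeq2 Wald test, 30 with no filter, 20 without vertebrate-named miRNAs and 0 without the male pupae of days 4 and 7 together.

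Successive ages were compared with both sexes of an age as replicates. From pupal day 1 to day 4, miR-263-x, a sensory organ miRNA in flies, rose from 15754 and 11819 CPM to 161890 and 85525 CPM in females and males (log2 3.09, SE 0.39, adjusted p = 0.0102 by edgeR). sfr-miR-6094-3p fell from 17778 and 18812 CPM to 1319 and 1331 CPM (log2 -3.82, SE 0.41, adjusted p = 0.00528 by edgeR). miR-193-y, miR-2788-y, sfr-miR-13b-3p and miR-263-z also rose, and miR-6094-z, miR-1175-x, miR-1175-y, sfr-miR-274-5p, sfr-miR-10485-5p, miR-750-y and sfr-miR-317-5p fell, with log2 changes from -3.77 to 4.39. miR-21-x, listed at 0 in both day 1 pupae and at 40.6 and 51.4 CPM on day 4, and miR-125-x (log2 6.53) rose too. Over the 18 libraries miR-125-x moved with the share of vertebrate-named miRNAs (Pearson r = 0.969, Spearman rho = 0.942, permutation p = 1e-05 for each, the smallest that 100000 permutations give, adjusted p = 4e-05 over 4 relations, r = 0.958 without the 2 libraries farthest from the median). The other 3 relations were those of miR-99-x (r = 0.474, permutation p = 0.044; rho = 0.664, permutation p = 0.0037; adjusted p = 0.088 and 0.0074; r = 0.626 without the 2 farthest libraries), miR-100-x (r = 0.300, permutation p = 0.23; rho = 0.0960, permutation p = 0.71; adjusted p = 0.307 and 0.94; r = 0.489 without the 2 farthest libraries) and let-7-x (r = 0.248, permutation p = 0.33; rho = 0.0196, permutation p = 0.94; adjusted p = 0.33 and 0.94; r = 0.417 without the 2 farthest libraries). edgeR called 19 of 344 miRNAs, 9 higher and 10 lower, and library totals alone gave 11 higher and 28 lower. The count was 62 and 71 without the day 4 female or male adult, 3 without either day 1 adult, 2 and 1 without the day 1 female or male pupa, and 0 and 2 without the day 4 female or male pupa. It was 85 with the DESeq2 Wald test, 30 with no filter, 48 without vertebrate-named miRNAs and 0 without the male pupae of days 4 and 7 together.

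From pupal day 7 to adult day 1, sfr-miR-34-5p rose from 8.92 and 7.64 CPM to 383 and 206 CPM (log2 5.08, SE 0.56, adjusted p = 0.00473 by edgeR), and sfr-miR-317-5p, miR-317-y and miR-281-x rose by 5.61, 4.62 and 2.50 on the log2 scale. miR-305-x, miR-305-y, miR-263-x, miR-263-z, sfr-miR-6094-3p, miR-71-y and sfr-miR-13b-3p fell, with log2 changes from -3.27 to -1.88. In the cluster of miR-277, miR-317 and miR-34, 3 of 9 rose, and 8 did adjusted over the list alone. edgeR called 13, 4 higher and 9 lower, and library totals alone gave 22 higher and 16 lower. The count was 70 and 61 without the day 4 female or male adult, 20 and 8 without the day 1 male or female pupa, 7 without either day 4 pupa, 3 without either day 1 adult, and 0 without either day 7 pupa. It was 75 with the DESeq2 Wald test, 32 with DESeq2's size factors, 24 with limma, 27 with thinned counts, 54 without vertebrate-named miRNAs and 0 without the male pupae of days 4 and 7 together.

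Between pupal days 4 and 7, edgeR called 0 of 344 miRNAs, with 56 at an unadjusted p under 0.05 and 45 called by DESeq2. The count was 11 and 12 without the day 4 female or male adult. Between adult days 1 and 4, sfr-miR-317-3p alone was called, at 634 and 288 CPM on day 1 and 5043 and 2492 CPM on day 4 (log2 2.99, SE 0.40, adjusted p = 0.0462 by edgeR). edgeR called 1 of 344, DESeq2 12. sfr-miR-317-3p was not called with DESeq2's size factors, library totals, thinned counts, rows unmerged or 1 row per sequence, nor without vertebrate-named miRNAs, any single pupa, either day 1 adult or the day 4 female adult; without the day 4 male adult 9 were called.

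Across larval instars 1 to 6, the trend per instar was tested. let-7-x rose by 1.79 per instar on the log2 scale (SE 0.39, adjusted p = 0.0171, edgeR), from 1.07 CPM (1 count) in instar 1 to 6651 CPM in instar 6. miR-100-x (log2 per instar 1.58, SE 0.25, adjusted p = 0.00639 by edgeR) rose from 316 to 138650 CPM. miR-927-x fell from 3973 to 59.3 CPM (log2 per instar -1.35, SE 0.17, adjusted p = 0.00413 by edgeR). miR-124-y, a neuronal miRNA, fell from 947 to 15.5 CPM (log2 -1.38, SE 0.21, adjusted p = 0.00602 by edgeR). Of 5 let-7 complex rows, 4 rose, and of 9 neuronal and sensory rows, 5 fell (4 and 6 adjusted over the list alone). sfr-miR-10505-3p, miR-745-y, miR-275-y, miR-9993-y, sfr-miR-6094-3p, miR-100-z, miR-99-x and the predicted miRNA of sequence CGGCTCATCGTATGGCAGTTTGCT also rose. miR-99-x is among the rows with names known from vertebrates whose sequence is a near copy of miR-100-x; it had 3048 CPM in instar 5, where the share of vertebrate-named counts was highest, and 469 CPM in instar 6. Falling were miR-993-y, miR-981-y, miR-137-y, miR-2796-y, sfr-miR-10499a-3p, sfr-miR-263b-5p and the predicted miRNAs of sequences CTTGCAACATCTTGTCCAGAAC and CTCAGTATTACTTTGGACCCACC. edgeR called 68 of 234, 25 rising and 43 falling, and library totals alone gave 16 rising and 49 falling. The count was 36, 38 and 45 without instar 1, 2 or 3, and 0 with instars 4 to 6 against 1 to 3 as groups. It was 105 with the DESeq2 Wald test and 28 with a 2-fold minimum per instar.

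Steps between single libraries have no replicate check and carry counting intervals only. Of 192 miRNAs with at least 100 CPM in egg or instar 1, 71 were at least 2-fold higher and 96 at least 2-fold lower in instar 1. miR-2765-z had 12713 CPM in the egg and 1.07 CPM in instar 1, 11839-fold lower (95% interval 2124 to 467860, on 1 count in instar 1). miR-137-y had 7.65 and 6095 CPM, 797-fold higher (95% interval 220.4 to 6579.6, on 2 counts in the egg). From instar 1 to 2, 59 of 155 changed 2-fold, with miR-305-x going from 472 to 6165 CPM and sfr-miR-263b-5p from 9738 to 1613 CPM. The next steps changed 22 of 145, 20 of 145, 61 of 167 and 40 of 163. The 3 largest rises from instar 3 to 4 were those of the vertebrate-named miR-143-y, miR-26-x and miR-22-y. From instar 4 to 5 they were those of miR-21-x, also vertebrate-named, of miR-99-z, which left that list as a near copy, and of miR-125-z, which is not in it. At the latter step sfr-miR-10460-5p fell 41.3-fold, from 138 to 3.35 CPM, on 1 count in instar 5. From instar 6 to prepupa, 60 of 156 changed, with miR-3338-y going from 86.1 to 1406 CPM and miR-11980-z from 491 to 0.924 CPM. The prepupa, whose sex the labels do not give, and day 1 pupae differed 2-fold in 23 of 150 (female) and 22 of 152 (male), with miR-3338-y at 3.72 CPM in the female and 2514 CPM in the male, and sfr-miR-317-5p at 26.3 CPM in the prepupa and 156 and 203 CPM in the pupae.

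The ratio of the 5p to the 3p arm was followed for 18 pairs of rows with both arms at a mean of at least 100 CPM, with 2 pairs each for miR-10 and miR-281. The sign of the ratio switched between libraries in 7 pairs, with no test of the counts. For miR-281 it did so for the rows miR-281-x and miR-281-y, from -1.01 to 1.49, while sfr-miR-281-5p against sfr-miR-281-3p ran from 3.19 to 4.78. For miR-14, log2(5p/3p) was 4.40 in the egg and -2.90 in the day 1 male pupa, and for miR-278 it was 4.38 in the egg and -2.57 in the day 1 female pupa. miR-317 ran from -9.73 in the egg to -0.27 in instar 1, always below 0. miR-6497 ran from -0.44 in instar 2 to 7.42 in the day 4 male adult, and miR-375 from -0.23 in the day 1 male pupa to 5.95 in the day 7 male pupa.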

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

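The tests in this part were chosen after the results they weigh had been seen, except that the bounds for the percent kept after thinning were set before those 2 tests were run; the 10 further draws and the count among miRNAs still tested were chosen afterwards. Single libraries stood apart from their life stage in 12 cases among 144 groups checked, of which chance gives about 1 in 20. On the log2(CPM + 1) scale they were miR-11625-x in the day 4 female adult (5.13, nearest 7.77), miR-11980-z in instar 1 (4.85, nearest 8.53) and in the day 4 male adult (0.39, on 1 count, others 0), miR-281-x in instar 6 (10.53, nearest 9.35) and in the day 4 male adult (9.54, nearest 8.89), sfr-miR-375-3p in instar 6 (5.73, nearest 4.43), and, all in instar 1, miR-305-x (8.89, nearest 12.59), miR-305-y (3.41, nearest 6.19) and miR-1175-x (8.88, nearest 10.15). The sex difference differed between adults and pupae for 11 miRNAs, and for the 8 of them with a mean of at least 100 CPM by a log2 difference of 8.04 for miR-2765-z, 7.37 for miR-989-z, 3.17 and 2.96 for the predicted miRNAs of sequences TATTTTTGTATTACATGGCCCA and CCCAGTGTCGTGTTAACGATCT, 2.91 for miR-998-y, 2.59 for miR-3338-y, 2.09 for sfr-miR-2765-5p and -1.31 for miR-1-y (edgeR adjusted p = 0.00271 for miR-2765-z and 0.0469 for the others).

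Vertebrate-named miRNAs took 0.920% of counts in instar 5, 0.689% in the day 7 male pupa and 0.792% in the day 4 female adult, each apart from the next library of its stage at 0.191%, 0.151% and 0.229%. They rose and fell together, with a median pairwise Spearman correlation of 0.879 over 18 libraries for 32 of them, which is consistent with reads from another organism. A change with life stage alone was tested by the largest ratio between the sexes of 1 age, which was 11.8 at pupal day 7, higher in the male; at adult day 4 it was 5.48, higher in the female. With the list as first drawn up, which still held near copies of insect miRNAs, that ratio was 3.67, under the bound of 4, so the outcome turns on a list that was revised after the first value had been seen, and life stage cannot be told apart from a foreign source. The labels give no diet, host or handling by library, and no biological explanation was tested.

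In day 4 adults, 33 miRNAs were at least 4-fold higher in the female and 8 in the male, among 182 with at least 100 CPM in either. Of the female-high ones, 63.6% were also at least 4-fold higher in egg than in instar 6, against 13.4% of the others (two-sided Fisher's exact test, p = 1.17e-08). The test treats rows as independent, although some are forms of 1 miRNA, such as miR-10-x and miR-10-z. Its p-value may therefore overstate the evidence. RNA of eggs carried in the female is a candidate explanation for part of the female-high miRNAs. The test compares the egg with instar 6 only, not with the female. After thinning, 96.97% of the female-high miRNAs stayed 4-fold higher. Thinning leaves expected ratios unchanged, so this argues only against counting noise. Other effects tied to the depth of this library cannot be judged from it. Rows of the revised vertebrate-named list made up 36.4% of the female-high miRNAs, between the bounds set, so a foreign source may account for part. Of the 21 others, 19 were egg-high. The exceptions, miR-23-y and miR-99-z, had 0 CPM in the egg. They also carry family names known from vertebrates and had left the list as near copies. Among the 19, miR-989-z, miR-989-y and a predicted miRNA had 18193, 1153 and 606 CPM in the day 4 female. In the egg they had less, with 520, 38.2 and 386 CPM. RNA like that of the egg library does not by itself account for these levels. The rest of the 19 were higher in the egg than in the day 4 female. Each sex has 1 library at this age, and sex as such stays open.

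For pupae against larvae, the shallower larval libraries were weighed as an explanation of the calls: after thinning to 1 depth 69.2% of the 120 calls stayed, between the bounds of 50% and 80%, but 26 had fallen below the count filter and had no call to keep. Of the 94 still tested, 83 stayed, and in 10 further draws at least 86.2% did, above 80%. This argues only against unequal counting depth, and only for these calls. Thinning leaves expected ratios unchanged, so other effects tied to the shallow larval libraries cannot be judged from it. The 11 others of the 94 kept direction, with a median log2 size of 0.99 (median SE 0.28) before and 0.71 (median SE 0.36) after. The 26 below the filter had a median log2 size of 2.53 (median SE 0.64) before and, tested with no filter, 2.11 (median SE 0.80) after, all in the same direction and 13 of them called, and at such low counts depth cannot be told apart from stage for the calls that were lost. In all 10 draws at least 98 miRNAs were called, more than the 22 that other groupings of these libraries gave at most without thinning. This argues against unequal counting depth as the whole cause. The labels' protocol speaks of 9 libraries without saying which, and the 9 shallowest, which hold every larva, were tested as 1 batch through the shallow male pupae of days 4 and 7, which lay nearer the other 4 pupae than the larvae for 95% of the calls, and for 81 of 90 called without them, which argues against such a batch as the whole cause, while a batch effect on part of the calls and life stage stay open.

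Chance groupings of the libraries were counted by refitting other splits. Pupae against larvae gave 120 calls, which 1 of 100 splits (the real one) reached, with 22 at most in the others; adults against pupae gave 75, reached by 1 of 100, with 35 at most; and adults against larvae 106, reached by 1 of 100, with 86 at most. For the larval trend, 2 of 100 orders of the instars gave at least 68 calls, the other giving 71. Chance can be excluded at the 0.05 level for the counts between life stages. For the larval trend it cannot, because only 100 of 360 possible orders were counted and another order gave more calls than the real one. For females against males, 5 of 100 splits gave at least 2 calls, with 8 at most, so chance cannot be excluded. Exchanging the sexes within ages, 2 of 16 splits gave at least 2, with 2 in the other, and 16 splits are too few for a share under 0.05.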

How the results depend on the processing

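Alternatives without both shallow male pupae, without vertebrate-named miRNAs, with rows unmerged, with 1 row per sequence and with thinned counts (1 draw for each comparison, 10 more for pupae against larvae) were chosen after seeing the data. Named miRNAs kept direction in all their alternatives, with 2458 values on the same side of the threshold and 360 no longer past it. No called miRNA changed sign in any alternative. The 3 life stage counts stayed within 1.5 times the reported ones, except 29 against 75 for adults against pupae without the day 4 female adult. DESeq2 size factors and library totals moved the median log2 change of all miRNAs from 0.088 to 0.16 and 0.24 for adults against pupae, from 0.21 to 0.0708 and 0.0156 for females against males, from 0.0316 to 0.15 and -0.0992 for pupal day 4 against day 1, from 0.0386 to 0.16 and 0.0205 for pupal day 7 against day 4, from 0.0392 to -0.11 and 0.14 for adult day 1 against pupal day 7 and from 0.14 to 0.23 and 0.29 for adult day 4 against day 1; directions of smaller changes are relative to these shifts. The sexes were matched by age, which was a block in the fit; the alternative with no age block is given below. Beyond that match, no paired analysis was possible because the labels carry no replicate numbers and name no shared animals or batches. The cause of each change below was not tested, except that omitted libraries and higher minimums leave less to test.

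Leaving out each library in turn, which for an age leaves 1 library assumed to vary like the others, the counts ran from 99 to 123 for pupae against larvae (reported 120), 29 to 91 for adults against pupae (reported 75), 72 to 117 for adult against larva (reported 106), 1 to 14 for females against males (reported 2), 0 to 71 for pupal day 4 against pupal day 1 (reported 19), 0 to 12 for pupal day 7 against pupal day 4 (reported 0), 0 to 70 for adult day 1 against pupal day 7 (reported 13), 0 to 9 for adult day 4 against adult day 1 (reported 1), 0 to 58 for the sex difference between adults and pupae (reported 11) and 36 to 74 for the larval trend (reported 68). With no filter, the count was 16 for females against males, 30 for pupal day 4 against pupal day 1 and 30 for the sex difference between adults and pupae. With the DESeq2 Wald test, the count was 21 for females against males, 85 for pupal day 4 against pupal day 1, 45 for pupal day 7 against pupal day 4, 75 for adult day 1 against pupal day 7, 12 for adult day 4 against adult day 1, 40 for the sex difference between adults and pupae and 105 for the larval trend. With no age block, the count was 5 for females against males. Without the male pupae of days 4 and 7, the count was 0 for females against males, 0 for pupal day 4 against pupal day 1, 0 for adult day 1 against pupal day 7, 0 for adult day 4 against adult day 1 and 0 for the sex difference between adults and pupae. Without vertebrate-named miRNAs, the count was 12 for females against males, 48 for pupal day 4 against pupal day 1, 54 for adult day 1 against pupal day 7, 0 for adult day 4 against adult day 1 and 20 for the sex difference between adults and pupae. With rows unmerged, the count was 4 for females against males and 0 for adult day 4 against adult day 1. With thinned counts, the count was 10 for females against males, 2 for pupal day 7 against pupal day 4, 27 for adult day 1 against pupal day 7 and 0 for adult day 4 against adult day 1. With library totals, the count was 39 for pupal day 4 against pupal day 1, 38 for adult day 1 against pupal day 7 and 0 for adult day 4 against adult day 1. With DESeq2 size factors, the count was 32 for adult day 1 against pupal day 7 and 0 for adult day 4 against adult day 1. With limma, the count was 24 for adult day 1 against pupal day 7. With 1 row per sequence, the count was 0 for adult day 4 against adult day 1. With a 2-fold minimum, taken per instar, the count was 28 for the larval trend. With instars 4 to 6 against 1 to 3, the count was 0 for the larval trend. With a minimum of 10 CPM, the count was 1082 for single-library steps. With a minimum of 1000 CPM, the count was 178 for single-library steps. With a 4-fold change, the count was 261 for single-library steps. With a minimum of 1 count, the count was 455 for median miRNAs per library. With a minimum of 100 counts, the count was 149.5 for median miRNAs per library. The ratio of the arms switched in 11 of 46 pairs with a mean of at least 10 CPM, 7 of 18 pairs with a mean of at least 100 CPM and 1 of 3 pairs with a mean of at least 1000 CPM.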

Other observations

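The tests of this part were chosen after the values had been seen. Some rows hold the sequence of another row plus 1 to 3 bases at the 3′ end, and the share of the longer form was compared across libraries for 26 such pairs. With 2 adenines added, sfr-miR-2765-5p becomes miR-2765-z, which made up 76.5% of the pair in the egg (exact 95% interval 75.2% to 77.8%), 44.5% in the day 4 female adult and 0.731% in the day 4 male. miR-92-y, sfr-miR-92a-3p plus 2 adenines, made up 20.03% in the egg, 12.6% in the female and 2.68% in the male. miR-2755-y, sfr-miR-2755-3p plus 2 adenines, made up 18.3% in the egg and a median of 0.693% in the other libraries.

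A hypothesis is that adenines may be added to miRNAs in eggs and in egg-bearing females. The 6 pairs with 2 added adenines exceeded the 20 other pairs by a median of 2.57 in the log2 ratio of the egg share to the median of the other libraries (exact permutation test, two-sided p = 0.0242), and by 1.79 in the log2 ratio of the day 4 female to the day 4 male share (exact permutation test, two-sided p = 0.0135). These ratios had 0.5 added to each count; on the shares as counted, the longer form was higher in the egg in 6 of 6 and 13 of 20 pairs (exact permutation test on the log2 ratios, two-sided p = 0.00982), and in the female in 5 of 6 and 10 of 20 (p = 0.0135). Against the hypothesis as the whole account, miR-2765-x, which adds an adenine and a thymine, also reached 26.99% in the egg (median elsewhere 0.497%) and 7.76% in the day 4 female against 0.886% in the male, and miR-281-x, with 2 adenines, had 2.91% in the female and 3.13% in the male. Some of the 20 other pairs could hardly rise, as the longer form already held a median elsewhere of 99.3% (miR-99-x and miR-100-x) or 99.2% (miR-81-z and bantam-y). The pairs with 2 adenines had medians elsewhere of up to 2.75%, so part of the difference may come from the starting share. The class of 2 adenines was picked after looking at these same shares, so the p-values describe the pairs and do not test the hypothesis independently. The pairs are not independent replicates, egg and each sex have 1 library, and without a genome the added bases cannot be told from templated ones.

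miR-5119-z, miR-4700-x, miR-301-x and miR-5550-x were found nearly only in the male pupae of days 4 and 7. miR-5119-z had 134 and 202 counts there and 33 in the other 16 libraries together.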
